A study of Homo sapiens with 6 samples.

How the data were processed

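The series holds 6 labelled libraries from TLE3 ChIP-seq in MDA-MB-453 cells. They are 2 siNS ChIP libraries, 2 siFOXA1 ChIP libraries and 2 input libraries, whose labels name the cell line as MDA-MB-454. The input libraries were not analysed here, and the labels do not say how they entered the peak calls. Per the labels' protocols, cells received a further cross-linking reagent before formaldehyde, and libraries were amplified from input and immunoprecipitated DNA. The labels call the libraries of a group biological replicates. Groups and replicate numbers were taken from the sample titles. For siFOXA1 2 the deposited list carries another number in its name, and the number of the title was used.

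The authors deposited 1 peak list per ChIP library, with no header and 5 columns (chromosome, start, end, name and score). Per the submitters' processing notes the tools were Trim Galore, BWA 0.7.5a, SAMtools and MACS2 and the build was hg38; settings, thresholds and the use of the inputs are not given in the sources used here. The score of each peak is the authors' deposited value and its definition is not stated. It starts just above 2 in each list (2.01 to 2.06) and was used only to rank peaks within a list. Each list belongs to 1 library, so lists could be compared between replicates. No list gives reads, coverage or depth, so no test on counts was possible, and a longer list can reflect depth, immunoprecipitation yield or binding. No pair of libraries shared more than 1 peak with the same start and end.

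Peaks on chromosomes 1 to 22, X and Y were used, which left out 4, 9, 4 and 3 mitochondrial peaks of siFOXA1 1, siFOXA1 2, siNS 1 and siNS 2. No peak lay on Y. Positions are given 1-based on hg38. Peaks that share at least 1 bp were merged. A consensus region of a group holds a peak of both its libraries, and a siNS consensus region counted as kept when a siFOXA1 peak overlapped it. Strength was the mean rank of a region's best score in the lists of its group, in 10 equal bins. Group means of values per library were compared with a two-sided exact permutation test. Regions within 1 kb of a gene end were compared with others by odds ratios, stratified by strength bin (Mantel-Haenszel) and computed for each siFOXA1 library. Chance overlap came from 100 circular shifts of at least 1 Mb along each chromosome, a comparison added after the data were seen.

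Gene positions came from a table of RefSeq genes on GRCh38.p14, whose chromosomes are those of hg38, with 20037 protein-coding genes. The table gives no strand, transcripts or exons, so transcription start sites, exons, introns and untranslated regions were not told apart. The planned distance to a start site was replaced by the distance to either end of a gene. Of the genes with a siNS consensus region at an end, 89.8% had it at 1 end only. Each region was assigned to the protein-coding gene whose span holds it or is nearest, within 100 kb, with overlapping genes separated by the nearer end. Assignment by distance does not show regulation. No genome sequence was used, so the 20 planned motif searches, the forkhead motif among them, were not run.

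The 13 gene lists (396 symbols, all matched, 1 through a synonym) were fixed before the data were examined, as were the main comparisons and most of the alternatives; the tests of the lists in siFOXA1, matching on genome length and the 3 list members named for siFOXA1 were added later. Genes with a region were counted per list and compared with other protein-coding genes by Fisher's exact test. The kept share of a list was compared with 10000 random lists matched on the number of siNS consensus regions per gene. Both were adjusted by Benjamini-Hochberg over the 13 lists with a threshold of 0.05. Genes and regions named in the text follow a rule set at the same time: 12 fixed genes, the 10 strongest regions of each class, the 10 genes with the most siNS-only and the 5 with the most common regions, and the 3 members of each list with the most siNS consensus regions. Some items that the rule selects are not reported here. Alternatives were a stricter score threshold, a larger overlap, widened peaks, lists of equal length, other distances, other rankings and leaving out each replicate. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9 were used.

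The code was tested on simulated data. It recovered all 7 simulated classes of 9000 regions, and its overlap counts equalled those of bedtools for 12 ordered library pairs. A stratified odds ratio simulated at 0.3 on 24961 regions was returned as 0.301 on average over 20 simulations. A list simulated at 40% kept against 20% elsewhere was called in 20 of 20 simulations of the kept-share comparison, and 3 of 240 unchanged lists were called. The simulated list was the corepressor list, with 108 siNS consensus regions, each kept independently of the others. Lists with fewer regions, down to 35 for neuronal genes, were not simulated at a raised share, so the power for them is not known.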

Results

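TLE3 occupancy was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in MDA-MB-453, a human breast cancer cell line. TLE3 is a Groucho-family corepressor that does not itself recognise DNA and is brought to chromatin by transcription factors. FOXA1, a forkhead pioneer factor of luminal breast cells, was silenced transiently in 2 libraries (siFOXA1 1 and 2) and not in 2 others (siNS 1 and 2). The comparison asks how far TLE3 binding needs FOXA1. Each library had its own list of peaks on the hg38 genome, with positions and a score per peak. The lists hold no read counts, so sequencing depth is unknown and FOXA1 levels were not measured by these data. The siNS lists held 45109 and 46589 peaks and the siFOXA1 lists 12253 and 13763.

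Fewer TLE3 peaks were called after FOXA1 silencing, and a smaller share of them lay at the ends of genes. On chromosomes 1 to 22 and X, siNS libraries had 45845.5 ± 1047 peaks and siFOXA1 libraries 13001.5 ± 1064 (mean ± SD, n = 2 each), a 3.53-fold difference. The sequence covered by peaks was 27.3 ± 0.404 Mb in siNS and 5.04 ± 0.516 Mb in siFOXA1, and the median peak width 432.5 ± 19.1 bp and 341.5 ± 7.78 bp. Within 1 kb of an end of a protein-coding gene lay 30.2% ± 2.2 of siNS peaks and 4.39% ± 0.24 of siFOXA1 peaks. Genes were overlapped by 66.1% ± 2.97 and 46.8% ± 0.159 of peaks. Chromosomes 16, 17, 19 and 22, a set chosen after the data were seen, held 20.9% ± 3.45 of siNS peaks and 8.64% ± 0.229 of siFOXA1 peaks. Each of these differences was larger than the spread between replicates, with both siNS libraries on one side of both siFOXA1 libraries. A two-sided exact permutation test over the 6 relabelings gave p = 0.333 for each, the smallest value that 2 against 2 libraries allow.

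**Figure D1:**
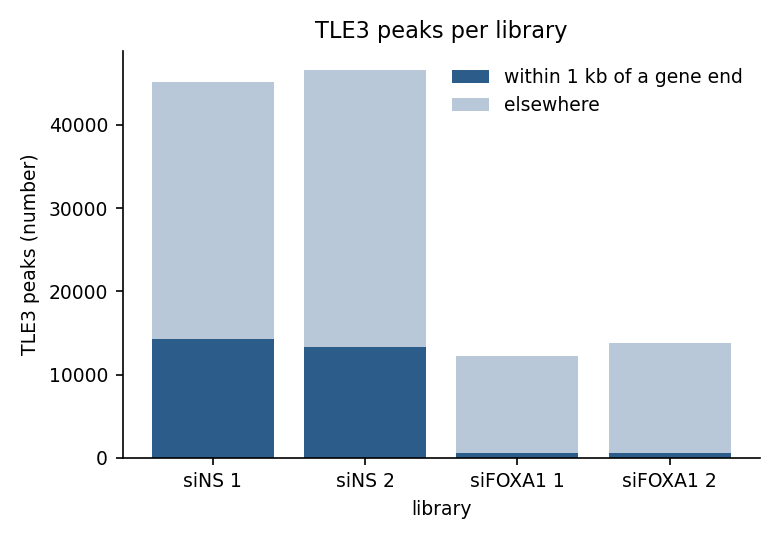
Number of TLE3 peaks (y axis) in each library (x axis), split into peaks within 1 kb of a protein-coding gene end (dark) and elsewhere (light). The siNS libraries have 45105 and 46586 peaks, with 31.7% and 28.6% near a gene end; the siFOXA1 libraries have 12249 and 13754 peaks, with 4.56% and 4.22%.

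Peaks were shared within each group more often than between the groups. Of siFOXA1 1 peaks, 67.6% overlapped a siFOXA1 2 peak, and 60.1% the other way. Of siNS 1 peaks, 58.0% overlapped a siNS 2 peak, and 58.9% the other way. Between the groups, 7.54% and 7.91% of siNS 1 peaks overlapped siFOXA1 1 and siFOXA1 2, against 13.6% and 14.2% of siNS 2 peaks. The siFOXA1 lists are the shorter ones, which limits these shares of siNS peaks. In the reverse direction the siNS libraries differed. Of siFOXA1 1 peaks, 28.0% were found in siNS 1 and 52.3% in siNS 2, and of siFOXA1 2 peaks 26.1% and 48.4%.

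Merging all 4 lists gave 72272 regions. The siNS-only class, with a peak in both siNS libraries and in neither siFOXA1 library, held 20732 regions (28.7%). The common class, with a peak in all 4 libraries, held 2602 (3.6%), and the siFOXA1-only class, with a peak in both siFOXA1 libraries and in neither siNS library, held 3282 (4.54%). The other 45656 regions were not shared by both libraries of a group or were found in 3 libraries. Of siNS-only regions 48.2% lay within 1 kb of a gene end, against 12.1% of common and 1.1% of siFOXA1-only regions. The siNS lists are the longer ones, and with lists of equal length the siNS-only count was far lower, as given below. The sizes of the siNS-only and siFOXA1-only classes therefore cannot be compared without regard to list length. Fewer libraries have to share or lack a peak when 1 is left out. The siNS-only class then held 38454 regions without siNS 1 and 40750 without siNS 2, and the common class 4837 without siNS 1. The siFOXA1-only class held 5574 without siNS 2, 6958 without siFOXA1 1 and 5728 without siFOXA1 2.

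**Figure D2:**
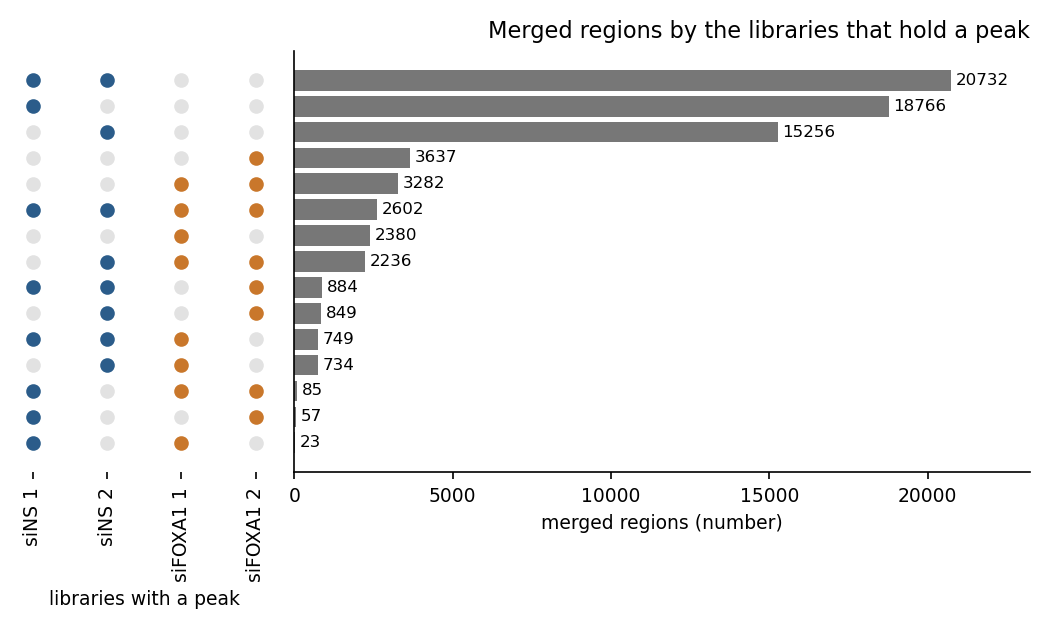
Number of merged regions (x axis) for each combination of libraries that hold a peak (filled dots on the left, siNS in blue and siFOXA1 in orange). The siNS-only class is the most frequent at 20732 regions, and 2236 regions were shared by both siFOXA1 libraries and siNS 2 but not siNS 1, against 85 with siNS 1 but not siNS 2.

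Most control TLE3 regions had no counterpart after FOXA1 silencing. Of 24961 siNS consensus regions (merged regions with a peak of both siNS libraries), 4229 overlapped a peak of at least 1 siFOXA1 library, which is 16.9% (exact 95% binomial interval 16.5 to 17.4%). The shares were 13.4% for siFOXA1 1 and 13.9% for siFOXA1 2, and 10.4% for both at once. Moving the siNS consensus regions along their chromosomes at random gave 0.81% overlap on average over 100 shifts (0.681 to 0.97%). The siFOXA1 lists are shorter than the siNS consensus, which limits the share, and with lists of equal length it was 32.3%. Without siNS 2 it was 9.66%. Binomial intervals here cover counting error over regions, not variation between cultures.

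Loss was more frequent at gene ends than elsewhere. Of 10652 siNS consensus regions within 1 kb of a gene end, 6.25% overlapped a siFOXA1 peak (5.8 to 6.73%), against 24.9% of the 14309 regions elsewhere (24.2 to 25.6%). Stronger siNS regions were kept more often. The weakest 10% by peak score were kept in 3.52% of cases and the strongest 10% in 58.3%. Among the strongest, 40.8% of regions near gene ends and 68.5% of the others were kept. With strength held in 10 bins, the odds of overlapping a siFOXA1 peak near a gene end were 0.138 times those elsewhere for siFOXA1 1 and 0.128 times for siFOXA1 2 (Mantel-Haenszel odds ratios). The crude odds ratios were 0.193 and 0.183. Regions are not independent replicates, so the range over both siFOXA1 libraries is given and no p-value. The kept share of the strongest 10% was 38.7% without siNS 2, and 22.4% when strength was taken from peak width.

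**Figure D3:**
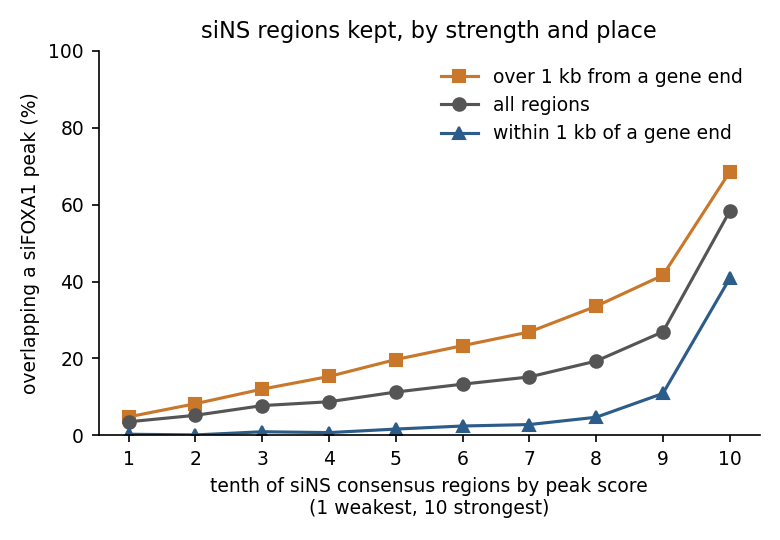
Share of siNS consensus regions that overlap a peak of at least 1 siFOXA1 library (y axis, percent) by strength bin from 1, weakest, to 10, strongest (x axis), for regions near gene ends (triangles), elsewhere (squares) and all (circles). In bin 10 the shares are 40.8%, 68.5% and 58.3%, and in bin 1 they are 0.282%, 4.81% and 3.52%.

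Most TLE3 regions at the 12 genes fixed in advance, among them luminal regulators, had no siFOXA1 peak. The 12 genes had 60 siNS consensus regions assigned, of which 16 overlapped a siFOXA1 peak, at 7 of the genes. This share was higher than the 16.9% of all 24961 siNS consensus regions, so the 12 genes did not stand out for loss. FOXA1 itself (chromosome 14, 37589552 to 37595249) had 4 siNS regions, of which 1 was kept. TLE3 (chromosome 15, 70047790 to 70097917) had 5, and none overlapped a siFOXA1 peak. It also had 2 siFOXA1 consensus regions, both with a siNS peak outside the siNS consensus. GATA3, the luminal zinc finger factor, had 7 siNS regions with none kept. It also had 3 siFOXA1 consensus regions, 1 of them without a siNS peak. ESR1, the oestrogen receptor, had 4 siNS regions and TFAP2B, an AP-2 factor, 3, again with none kept and no siFOXA1 consensus region. XBP1 kept 1 of 4, ERBB2 1 of 5 and MYC 2 of 7. SPDEF, an ETS factor of luminal secretory cells, kept 5 of 9, and HES1, a Notch-responsive repressor that works through Groucho proteins, kept 5 of 10. KRT5, a basal keratin, had no consensus region in either group. No XBP1 region was kept without siFOXA1 1 or without siNS 2, and 11.1% of ERBB2 regions without siNS 2. Without siFOXA1 2, 33.3% of SPDEF and 14.3% of MYC regions were kept. Without siNS 1, when peaks of siNS 2 alone count, 30.8% of TLE3 and 11.8% of GATA3 regions were kept.

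The genes with the most siNS-only regions included a corepressor gene and a transcription factor gene. BCOR, a BCL6 corepressor gene on chromosome X, had 25 siNS-only regions and 1 of its 26 siNS consensus regions kept. GSE1 had 21, LOC124905135 and ZMIZ1 19 each, and CASZ1, a zinc finger factor, 18. AGAP1, CCDC85C, HIVEP3 and SHANK2 had 15 each, and GNG7 14. The length of genome assigned to these genes ranged from 98 kb for CCDC85C to 888 kb for SHANK2, and the counts are not adjusted for it. GSE1 also had the most common regions, with 16, and 19 of its 40 siNS consensus regions were kept. EEFSEC and RXRA, the retinoid X receptor, had 6 common regions each, and ARSG and DGLUCY 5 each.

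The strongest siNS-only regions, by the authors' peak score within each siNS list, lay inside genes in 4 of 10 cases and within 1 kb of a gene end in 2. The first was inside FURIN, a proprotein convertase gene (chromosome 15, 90873595 to 90874746), with scores of 658 in siNS 1 and 598 in siNS 2. Others were at an end of PERCC1 (chromosome 16, 1430405 to 1431462), inside KLHDC4, inside RET, a receptor tyrosine kinase gene (chromosome 10, 43092484 to 43094761), at an end of RDH13 and inside BMP7. The remaining 4 lay between genes, nearest to LOC124905027, RPLP1 and, for 2 of them, METRNL. Of the 10 strongest common regions 6 lay within 1 kb of a gene end, including those at ELF3, an epithelial ETS factor (chromosome 1, 202017582 to 202019602), TRIB1, a pseudokinase gene (chromosome 8, 125429072 to 125432321), HID1, MB, PRRT1B and LOC124904102. The others were inside NFIX and PAX9, near AQP7, and on chromosome 15 (69593685 to 69596131) with no protein-coding gene within 100 kb. The 10 common regions scored 461 to 790 in the siNS lists. In the siFOXA1 lists they scored from 9.3, for the region on chromosome 15, to 124 at NFIX. The median scores of the siFOXA1 lists were 9.57 and 10.3. A common or kept region thus had a called peak, which need not rank as high as in siNS. None of the 10 strongest siFOXA1-only regions was near a gene end.

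Some TLE3 regions of the siFOXA1 libraries lay where the control lists had no peak. The siFOXA1 consensus held 8218 regions, of which 39.9% overlapped no siNS peak (38.9 to 41.0%), 32.2% overlapped siNS 1 and 59.0% siNS 2. Only 4.28% of siFOXA1 consensus regions lay within 1 kb of a gene end, against 42.7% of siNS consensus regions. Random shifts placed 2.99 and 4.27% there, so siNS regions exceeded the shifted level 9.98-fold and siFOXA1 regions 1.43-fold. The siFOXA1-only regions lay there in 1.1%, against 2.71% after shifts (2.1 to 3.47%). Their choice contributes to this, because it removed the regions with a siNS peak, 316 of the 352 siFOXA1 consensus regions near a gene end. Among the 10 strongest siFOXA1-only regions, 1 lay 52457 bp from SAMSN1 (chromosome 21, 14711874 to 14712923), with scores of 253 in siFOXA1 1 and 324 in siFOXA1 2. Those inside genes were in TAS2R1, FAR2, NPR3, a natriuretic peptide receptor gene, CHN2 and GALNT7. SPTSSA and PAIP1 were the nearest genes to 2 more, and 1 on chromosome X had no protein-coding gene within 100 kb.

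Control TLE3 regions lay next to corepressor, luminal and signalling genes more often than next to other genes. Of 20037 protein-coding genes, 12337 had a siNS consensus region assigned, and 8 of the 13 gene lists passed the adjusted threshold, each above the 61.5% of other genes. The other genes are all remaining protein-coding genes, whether or not these cells express them. Neither this comparison nor the one for siFOXA1 below was matched on expression, so an excess was not separated from expression in general. All 27 genes of the Groucho/TLE and corepressor list had one, among them HDAC4 with 15 regions and ID1 with 8. Luminal identity genes had one in 32 of 35 cases, with 12 regions at KRT7, 10 at TFAP2A and 9 at SPDEF. Wnt genes had one in 29 of 32 cases, with 13 regions at WNT7B, 8 at NKD1 and 7 at AXIN2. The HER2, PI3K and receptor tyrosine kinase list also had one in 29 of 32 cases, with 11 at SPRED2, 10 at FGFR4 and 6 at IGF1R. Two-sided Fisher's exact tests with Benjamini-Hochberg adjustment gave adjusted p = 3.65e-05 for corepressors, 0.001 for luminal identity and 0.00125 for each of the Wnt and HER2 lists.

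Notch genes had a siNS region in 23 of 27 cases, with 10 at HES1 and 6 each at DLL1 and JAG2. Glucocorticoid response genes had one in 21 of 24, with 9 at CEBPB, 7 at TSC22D3 and 6 at GADD45B. Oestrogen response genes had one in 21 of 25, with 9 at RET, 8 at RARA and 7 at FOS. Cell cycle genes had one in 26 of 32, with 8 at MCM5, 5 at CDKN1A and 4 at CDC25B. Fisher's exact test gave adjusted p = 0.0219 for the Notch and glucocorticoid lists, 0.042 for the oestrogen list and 0.0447 for the cell cycle list. These 4 lists did not pass without siNS 1, and the Notch and oestrogen lists did not pass without siNS 2, where the mesenchymal list passed. Matched on the length of genome assigned to each gene, the oestrogen list did not pass and the ribosomal list did.

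The other 5 lists did not pass. Ribosomal protein genes had a siNS region assigned in 26 of 34 cases, with 7 each at RPL3 and RPLP1 and 2 at RPL13. Each region is assigned to 1 gene only. Without assignment, 29 of the 34 had a siNS region within 1 kb of an end, so this list's result depends on the assignment rule. Basal genes had one in 23 of 34, with 5 at CDH3 and 4 each at EN1 and ITGA6. Mesenchymal and invasion genes had one in 23 of 34, with 5 each at SNAI1 and TGFB1 and 4 at MMP2. Androgen response and apocrine genes had one in 21 of 34, with 9 at PMEPA1, 7 at ZBTB16 and 6 at NDRG1. Neuronal genes had one in 14 of 26, with 11 at RBFOX3, 7 at TH and 3 at SNAP25. Fisher's exact test gave adjusted p = 0.115 for ribosomal, 0.647 for basal and for mesenchymal, 1 for androgen response and 0.554 for neuronal genes.

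In the siFOXA1 libraries TLE3 regions lay next to luminal identity, androgen response and oestrogen response genes more often than next to other genes, in tests chosen after the data were seen. Of 35 luminal identity genes 19 had a siFOXA1 consensus region, against 19.2% of other genes, with 5 regions each at ELF3 and GRHL2 and 4 at ERBB4. Androgen response and apocrine genes had one in 16 of 34 cases, with 4 each at CLDN8 and ZBTB16 and 3 at ABCC11. Oestrogen response genes had one in 13 of 25, with 3 each at NHERF1 and PKIB and 2 at CISH. Corepressor genes had one in 12 of 27, and the Wnt and HER2 lists in 12 of 32 each. Fisher's exact test gave adjusted p = 5.47e-05 for luminal identity, 0.00109 for androgen and for oestrogen response, 0.00816 for corepressors and 0.0469 for the Wnt and HER2 lists. The oestrogen, Wnt and HER2 lists did not pass with peaks at or above the median score of their list, nor with genes within 10 kb.

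The other 7 lists did not pass in siFOXA1. Notch genes had a region in 10 of 27 cases, basal genes in 11 of 34, glucocorticoid response genes in 8 of 24, mesenchymal genes in 10 of 34 and neuronal genes in 8 of 26. Cell cycle genes had one in 2 of 32 and ribosomal protein genes in 2 of 34. Fisher's exact test gave adjusted p = 0.0504 for Notch genes and 0.0797 to 0.139 for the others. Without siFOXA1 2 the Notch, glucocorticoid and ribosomal lists passed, the ribosomal list with a lower share than other genes. Notch genes also passed within 10 kb and by the nearest gene end, and basal genes with peaks at or above the median score. Matched on the length of genome assigned to each gene, 3 lists passed, namely luminal identity, androgen response and oestrogen response. With siFOXA1 regions that overlap no siNS peak no list passed by Fisher's exact test, and 2 (luminal identity and neuronal) had an unadjusted p under 0.05.

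**Figure D4:**
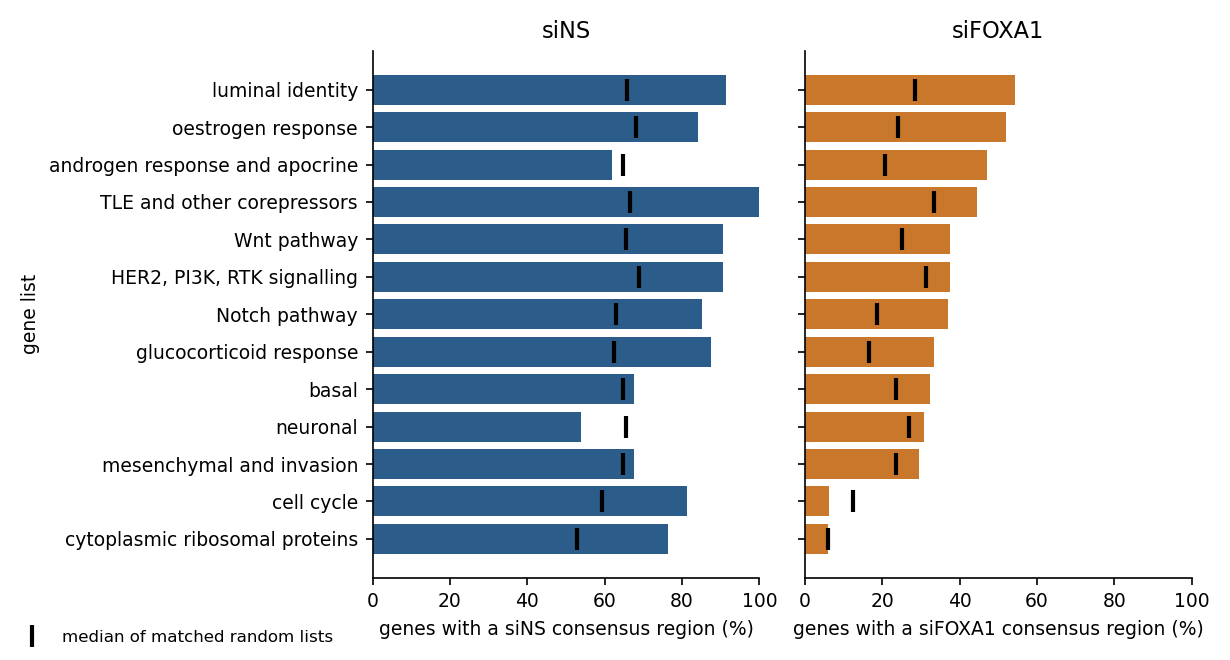
Share of the genes of each list (y axis) with a consensus region assigned in siNS (left) or siFOXA1 (right), in percent (x axis). Black ticks are the median of 10000 random lists matched on the length of genome assigned to each gene; in siFOXA1 luminal identity genes reach 54.3% against a median of 28.6%.

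No gene list kept its control regions at a rate that passed the adjusted threshold, and 3 of the 13 lists had an unadjusted p under 0.05. These were the oestrogen response list, which kept 35.6% of its siNS consensus regions (26 of 73), the androgen response and apocrine list with 33.8% (24 of 71) and the basal list with 31.6% (18 of 57). A permutation test with random lists matched on regions per gene gave each of them adjusted p = 0.0884. Luminal identity genes kept 29.6% (40 of 135) and neuronal genes 5.71% (2 of 35), each with adjusted p = 0.171 in the same permutation test. Notch genes kept 24.0%, mesenchymal genes 20%, glucocorticoid response genes 18.3%, the HER2 list 18.2%, corepressors 17.6%, Wnt genes 15.6%, cell cycle genes 11.8% and ribosomal protein genes 9.09%. The permutation test gave adjusted p = 0.592 to 0.931 for these 8, and random lists had medians between 14.0 and 22.1% over all 13. Without siNS 2, 4 lists passed (androgen response, basal, luminal identity and oestrogen response, each kept more often than in random lists), and without siFOXA1 1 the androgen response and basal lists passed. With regions over 1 kb from a gene end no list passed, and only the basal and neuronal lists had an unadjusted p under 0.05. With peaks at or above the median score the oestrogen list lay only 0.337 percentage points above its random median. Random lists were not matched on the share of regions at gene ends, where fewer regions were kept. The p-values describe these 4 libraries and do not test the treatment.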

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

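Tests of the odds ratio at gene ends and of siNS 1 sensitivity were set after related values had been seen. The test of nesting of siFOXA1 regions was set with the overlap between the siNS lists already known. The other tests of this part were set before. The mitochondrial sequence, which the comparisons leave out, held 9 peaks in siFOXA1 2 against 4 and 3 in siNS 1 and siNS 2, and 4 in siFOXA1 1.

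The siFOXA1 lists were 3.53-fold shorter than the siNS lists. A lower depth or yield alone would keep nearly all of the strongest 10% of siNS consensus regions, but 58.3% were kept (22.4% with strength taken from peak width and 77.1% with lists of equal length). A yield effect would also nest siFOXA1 regions in the siNS lists. Of all siFOXA1 consensus regions 60.1% overlapped a siNS peak, near the 58.0% and 58.9% of peaks shared between the siNS lists. That share does not count against a yield effect. Yet 31.9% of the strongest 10% of siFOXA1 consensus regions overlapped no siNS peak, with 39.0% found in siNS 1 and 65.9% in siNS 2. Between the siNS lists, 0% (siNS 1) and 13.2% (siNS 2) of the strongest 10% of peaks were missing from the other list. The fullest 1% of 1 Mb windows (30 of 3042) held 6.49% of siFOXA1-only regions, against 7.8% of siNS-only and 10.6% of common regions. The siFOXA1-only regions thus piled up in a few windows no more than the other classes. Copy number as a cause was not tested by this, because both groups are the same cell line. A change of TLE3 binding with FOXA1 silencing stays open as a hypothesis, as do differences in immunoprecipitation or input between the groups, which the lists cannot show.

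Regions at gene ends were lost more often than others. Peak strength alone would give a stratified odds ratio near 1, but it was 0.138 in the siFOXA1 library closer to 1 and at most 0.204 under the other settings. Unspecific signal at the ends of highly transcribed genes in the siNS libraries may contribute. Without assigning regions to single genes, 85.3% of ribosomal protein genes (exact 95% interval 68.9 to 95%) had a siNS region at an end. This was 1.55 times the 55.0% of other genes. A ratio of 1.5 lies inside the exact interval, and TLE3 bound at active genes would give the same, so these cannot be told apart. FOXA1-dependent binding at gene ends remains an untested alternative.

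Regions with both siFOXA1 libraries and siNS 2 but not siNS 1 numbered 2236, against 85 with siNS 1 but not siNS 2. A lower sensitivity of siNS 1 stays open: siNS 1 peaks missing from siNS 2 were 1.02 times as frequent as the reverse, but lists of nearly equal length hold that ratio near 1. Each list was split by score into 10 bins after the data were seen. In the strongest 10%, 0 of 4511 siNS 1 peaks were missing from siNS 2, against 617 of 4659 siNS 2 peaks (13.2%) missing from siNS 1. Bins 6 to 10 had this order, and bins 1 (weakest) to 5 the reverse. In bin 1, 86.1% of siNS 1 peaks and 66.5% of siNS 2 peaks were missing from the other list. In bin 5 the shares were 54.1% and 44.3%. The direction thus changed with peak strength, so these shares do not settle the sensitivity of siNS 1. Carry-over of siFOXA1-like material into siNS 2 could add siFOXA1 regions shared with siNS 2 but not siNS 1. The share of siFOXA1 consensus regions with a siNS 2 peak was 15.5 percentage points higher in the strongest than in the weakest 10%. That is less than strong carry-over predicts and more than none, and the difference for siNS 1 was 13.3 points, so carry-over, a lower sensitivity of siNS 1 and a difference between the cultures cannot be told apart.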

How the results depend on the processing

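Of 92 alternative values for the main results, 46 stayed within 1.5 times the count or within 1 SD between libraries, and no main comparison changed direction; where values moved, the cause was not tested unless given. The peak ratio of 3.53 was 5.41 for base pairs covered. With peaks at or above the median score of their list, siNS-only, common and siFOXA1-only regions numbered 12880, 1303 and 1919, the kept share was 14.2%, that of the strongest 10% 50.9%, the odds ratio at gene ends 0.142, and 2 lists (androgen response and basal) passed for kept share. With lists of equal length (12249 peaks), siNS-only and common regions numbered 5172 and 1578, since fewer siNS peaks then entered. In that setting the kept share was 32.3%, that of the strongest 10% 77.1% and the odds ratio 0.204. Widening peaks by 200 bp gave a kept share of 18.0%, and regions over 1 kb from a gene end 24.9%. Requiring a peak in both siFOXA1 libraries gave 41.2% for the strongest 10%, an odds ratio of 0.119 and 1 list (androgen response). Ranking by width gave 22.4% for the strongest 10%. The odds ratio was 0.193 for gene ends within 5 kb, 0.171 with the ends of all genes but pseudogenes and 0.169 for regions wider than the median. With genes within 10 kb, 1 list (androgen response) passed for kept share. For siFOXA1 binding, 3 lists passed when matched on assigned genome length and 0 with regions lacking a siNS peak, where the corepressor list lay at -0.459 percentage points from other genes. Leaving out each replicate in turn gave 21484 to 40750 siNS-only, 2634 to 4837 common and 3369 to 6958 siFOXA1-only regions, kept shares of 9.66 to 17.5%, 38.7 to 59.3% for the strongest 10%, 0 to 4 lists for kept share and 4 to 7 lists for siNS binding. Alternatives added after the data were seen were the other gene ends, wide regions, distal regions, nearest gene end, matching on genome length, the siNS binding lists without a replicate and all siFOXA1 binding lists. The replicate numbers were not shown to pair the libraries (correlation of replicate differences 0.00415 over regions, 2 numbers only). With the replicate block, which compares same-numbered libraries, the peak ratio was 3.53 (exact sign-flip p = 0.5, the smallest possible), siNS-only, common and siFOXA1-only regions averaged 40837, 4964 and 7961.5, and the kept share 10.9%, because single lists replace consensus regions. Among 325 alternative values for single gene lists 285 kept their side of the threshold, and among 107 for the fixed genes 96 stayed within their binomial interval. The 325 values, and the 92 for the main results, include siFOXA1 binding without siNS 1 or without siNS 2. No siNS peak enters there, so these values repeat the reported ones and say nothing on stability. Depth is unknown, so a region without a peak was not detected at the authors' threshold, which does not show that TLE3 was absent. The planned forkhead motif comparison and its alternatives were not run for want of a genome sequence.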

Other observations

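The genes with the most siFOXA1-only regions, a set named after its values were seen, differed from those with the most siNS-only regions. MACROD2 had 10 of them, LRP1B and RAD51B 8 each, DLG2 7, and HEMK2, LINGO2, NAALADL2, NFIA, NPAS3 and NRG3 6 each. The length of genome assigned to these 10 genes ranged from 431 kb for HEMK2 to 2258 kb for DLG2, so long genes have more room for regions. NFIA, a nuclear factor I gene, had 8 siNS consensus regions, 2 of them kept. TP63, the regulator of basal epithelial cells, had 6 siFOXA1 consensus regions, 4 without a siNS peak, and none of its 3 siNS consensus regions overlapped a siFOXA1 peak. CLDN8, a claudin of the androgen response list, had 4 siFOXA1 consensus regions, 3 of them without a siNS peak, and no siNS consensus region.

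Among list genes with at least 3 control regions, 4 kept each of them. ELF3 kept 6 of 6 siNS consensus regions, CISH 4 of 4, and SFRP1, a secreted Wnt antagonist, and RBPJ, the Notch transcription factor, 3 of 3 each. None of the 10 regions at FGFR4, 9 each at CEBPB and RET and 8 at MCM5 overlapped a siFOXA1 peak. These genes were chosen after their values were seen.

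Regions found in a single siNS library also differed in place. Of 18766 regions with a peak of siNS 1 alone, 17.2% lay within 1 kb of a gene end, against 7.98% of the 15256 regions with a peak of siNS 2 alone. Chromosome 19 held 7.27% of siNS 1 peaks and 5.25% of siNS 2 peaks, and 1.61% and 1.5% of siFOXA1 1 and siFOXA1 2 peaks, while it carries 7.24% of protein-coding genes.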
